A study of Mus musculus with 24 samples.

How the data were processed

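Poly(A) RNA was isolated from 24 liver samples, prepared as NEBNext Ultra II Directional libraries and sequenced on an Illumina NextSeq instrument, per the labels. The authors aligned reads with STAR 2.7.0f to GRCm38. The read counter, its strand setting and the annotation release are not given in the sources used here. The deposited table holds raw counts, whole numbers per Ensembl gene, for 55536 genes and 24 libraries, and all sample columns were used. Gene symbols, coordinates, transcript length and GC content came from the GENCODE M21 annotation of GRCm38. A total of 86 genes without a symbol, 0.0205% of counts, were kept in the fit. Libraries held 8734013 to 14711368 counts. Within each group the chi-square per gene between any pair of libraries was at least 8.03, so no pair was a near copy of another.

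Samples were assigned to lean chow, vehicle and semaglutide from the labels, 8 each. Replicate numbers are shared between groups but are not said to pair samples. Library names follow the replicate numbers, so libraries of the same number stand next to each other in that series. Whether they were handled together is not stated. Before the data were examined, the comparisons, tests, 36 gene lists, rule for named genes and most alternatives were fixed. Counts were analysed in R 4.3.3 with edgeR 4.0.16. Genes were kept by filterByExpr on group (minimum count 10, minimum total 15), which left 13358 genes with 99.9% of counts. Libraries were scaled with TMM, and 1 quasi-likelihood model with a coefficient per group was fitted to all 24 libraries. P-values were adjusted by Benjamini-Hochberg over all tested genes of a comparison and called at 0.05. The standard error of a log2 fold change is its size divided by the square root of the F statistic. Log2 CPM used a prior count of 2.

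The gene lists held 889 genes, 774 of them tested, with 37 in more than 1 list. They were tested with camera on voom values (limma 3.58.1) with a preset correlation of 0.01, adjusted over the 36 lists. Each was tested again with an estimated correlation and with fry, which asks whether the genes of a list move on balance in 1 direction without comparing them with other genes. Members called were counted from the edgeR fit, adjusted over all genes and over the list alone. A list score is the mean log2 CPM difference of its tested members from their mean over the libraries.

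Named genes followed a rule with 3 parts. A panel (Glp1r, Gcgr, Col1a1, Acta2, Timp1, Trem2, Cyp7a1 and Fgf21) is given in each comparison. In the first 2 comparisons, up to 2 members with the smallest adjusted p past the threshold were taken from each of the 12 main lists. The 5 highest and 5 lowest log2 fold changes among called genes with a mean log2 CPM of at least 2 and a named symbol were taken in all 3. Genes outside it are marked as named after their values were seen. Some named genes belong to families with near-identical members (Mup7, Serpina1e, Serpina4-ps1, Saa2, Saa3, Orm2, Gsta1, Cyp2b10, Cyp4a14, Ugt2b5, Acot1, Rdh16f2), whose reads may be shared or lost. Timp1 with Syn1, Col4a1 with Col4a2, Hsd3b5 with Zfp697 and Mmp12 with Mmp1b overlap on opposite strands, and Tm7sf2 with Vps51 on the same strand.

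Measures of the libraries were compared by exact two-sided permutation of group labels, adjusted over all such tests. For the covariance of fold changes, vehicle libraries were divided into disjoint sets in 70 ways, and the vehicle and semaglutide labels were permuted in all 12870 ways. Opposite calls were also counted from a fit with odd and even vehicle replicates as separate groups. Each comparison's count was repeated over 100 splits of its 16 libraries. Dixon's ratio, the gap of the extreme library divided by the range, was computed for library measures, named genes and list scores. For vehicle replicate 2, its interval with the trend removed came from 2000 resamples of a list's genes. Dixon's ratio was limited to lists with at least 5 tested genes after a first look at the values.

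The pipeline was tested on simulated data with 13358 genes. For semaglutide against vehicle, it recovered 28.4% of genes changed 1.5-fold, 77.6% of those changed 2-fold and 97.0% of those changed 4-fold, with 7 false calls of 142. Each gene was drawn independently of the others, so no simulated library stood apart from its group. Real libraries did, so these rates need not hold for the real data. The alternatives fixed beforehand were RLE size factors, the DESeq2 1.42.0 Wald test, voom with quality weights, no filter, a stricter filter (1 CPM in 8 libraries), fits of only the groups compared, a replicate block and leaving out each library. Added after seeing the data were covariates for the slopes of log2 CPM on transcript length and GC content, and gene list tests without lean chow replicate 2 and without vehicle replicate 2. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15. No library was excluded from the reported results.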

Results

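Polyadenylated RNA was sequenced from 24 mouse liver samples in 3 groups of 8. The groups were lean mice on chow given vehicle, per the labels (called lean chow), mice with diet-induced metabolic dysfunction-associated steatohepatitis (MASH) given vehicle (called vehicle), and MASH mice given semaglutide, a GLP-1 receptor agonist. The MASH mice ate the GAN diet, a Western-type diet high in fat, fructose and cholesterol, and had MASH and fibrosis on liver biopsy. Semaglutide was injected under the skin each day at 30 nmol/kg over 12 weeks. Libraries held 8734013 to 14711368 counts. Their means were 12094358 ± 1439331 in lean chow, 11785096 ± 867084 in vehicle and 12157938 ± 2156035 in semaglutide (SD, n = 8 each). Exact permutation tests between the groups gave p = 0.610 to 0.944. The labels number the samples 1 to 8 in each group without stating that each came from its own mouse, so p-values measure the spread between these samples. Levels are normalised read counts (CPM, scaled with TMM factors), and gene positions are on GRCm38.

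On the first principal component of log2 CPM, which held 42.1% of the variance, lean chow libraries averaged -53.7 ± 14, vehicle 36.3 ± 16.3 and semaglutide 17.4 ± 11.8 (SD, n = 8 each). Vehicle and semaglutide each differed from lean chow by an exact two-sided permutation test (p = 0.000155, the smallest it can give, adjusted p = 0.00140 over the tests of library measures). Semaglutide against vehicle gave an exact p = 0.0215, which did not pass the adjustment (adjusted p = 0.0965). Lean chow replicate 2, at -25.3, lay nearest of its group to the vehicle and semaglutide groups. Vehicle replicate 2, at 1.80, lay nearest of its group to lean chow. Albumin, the main plasma protein of hepatocytes, took 8.98 ± 1.31% of counts in lean chow, 5.52 ± 0.644% in vehicle and 6.65 ± 0.844% in semaglutide.

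**Figure D1:**
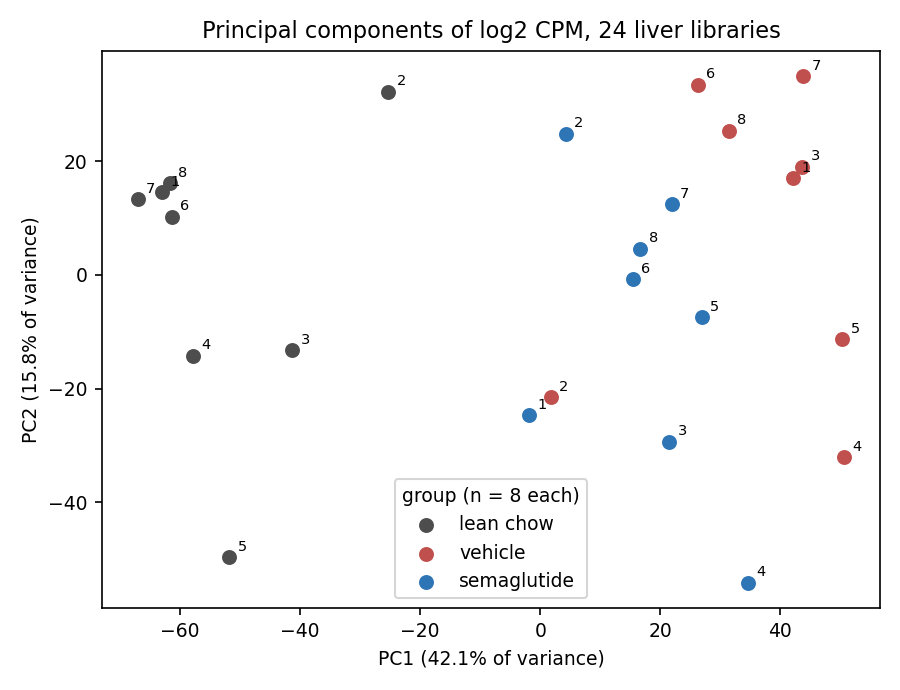
Each point is 1 of the 24 libraries on the first 2 principal components of log2 CPM, with the percent of variance on each axis and 8 libraries per group. Lean chow averaged -53.7, vehicle 36.3 and semaglutide 17.4 on the first component, and vehicle replicate 2 lay at 1.80.

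The first comparison asked how vehicle-treated MASH livers differed from lean chow livers. Most collagen and matrix genes, lipid-associated macrophage markers and cell cycle genes rose in vehicle livers, while most genes of cholesterol synthesis and most male-biased liver genes fell. Col1a1, a chain of fibrillar collagen, rose from 10.8 ± 5.93 CPM in lean chow to 137.7 ± 49.6 CPM in vehicle (SD, n = 8 each). Mmp12, a macrophage elastase, rose from 0.790 ± 0.578 to 62.96 ± 22.2 CPM. Sqle, the squalene epoxidase of cholesterol synthesis, fell from 119.6 ± 32.8 to 2.24 ± 1.32 CPM. By the edgeR quasi-likelihood test with Benjamini-Hochberg adjustment, 2630 of 13358 tested genes were higher and 2622 lower in vehicle at an adjusted p of 0.05. Of these, 1533 and 356 also changed at least 2-fold.

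Fold changes were ranked among called genes with a mean log2 CPM of at least 2 and a named symbol. Among the 5 highest fold changes, Ephb2 (ENSMUSG00000028664, chromosome 4, 136647539 to 136835988), an ephrin receptor kinase, rose by a log2 fold change of 6.96 ± 0.60 (SE, n = 8 per group). Mmp12 (ENSMUSG00000049723, chromosome 9, 7344381 to 7369499) rose by 6.25 ± 0.38. Gpnmb, a lysosomal glycoprotein of lipid-laden macrophages, rose by 5.74 ± 0.53. H19, a long noncoding RNA of fetal liver, rose by 5.54 ± 0.91, and Ly6d, a GPI-anchored surface protein, by 5.38 ± 0.62. Lean chow replicate 5 held far more Gpnmb than the other 7 lean chow libraries, and without it the log2 fold change of Gpnmb was 7.32. Without lean chow replicate 2 that of Ly6d was 6.10. Among the lowest, Hsd3b5 (ENSMUSG00000038092, chromosome 3, 98618634 to 98630252), a male-biased hydroxysteroid dehydrogenase, had a log2 fold change of -8.64 ± 1.29. Mup7, a major urinary protein, reached -5.80 ± 1.15, and Sqle (ENSMUSG00000022351, chromosome 15, 59315077 to 59331192) reached -5.72 ± 0.39. Slco1a1, an organic anion transporter, reached -5.67 ± 0.89, and Serpina1e, an alpha-1 antitrypsin gene, reached -5.59 ± 0.96. In vehicle, Hsd3b5 and Serpina1e were highest in replicate 2 and Ephb2 was lowest there. Without that library Hsd3b5 had a log2 fold change of -10.1, Mup7 -7.36, Serpina1e -6.80 and Slco1a1 -6.29. Ephb2 and H19 averaged 0.226 and 0.120 CPM in lean chow, and Hsd3b5 0.316 CPM in vehicle. The sizes of these fold changes therefore rest on very few counts in that group.

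Of 40 tested collagen and matrix genes, 39 rose and 1 fell (also 39 and 1 adjusted over the list alone), with a median log2 fold change of 1.82. The gene that fell, named after its values were seen, was Col5a3, a minor fibrillar collagen chain, at -0.92. The camera test with preset correlation called the list (adjusted p = 4.21e-24), with adjusted p = 0.0519 with an estimated correlation. Col3a1 rose by 3.02 ± 0.27 and Col1a2 by 2.94 ± 0.26, both fibrillar collagen chains, Col1a1 by 3.67 ± 0.33, and Timp1, an inhibitor of matrix metalloproteinases, by 4.36 ± 0.45. Timp1 overlaps Syn1 on the other strand. Of 27 stellate cell and myofibroblast markers, 18 rose and 1 fell (18 and 1 adjusted over the list alone), and the list was called with the preset and with the estimated correlation (camera adjusted p = 1.08e-06 and 0.0103). Vim, an intermediate filament of mesenchymal cells, rose by 1.97 ± 0.16 and Acta2, smooth muscle actin, by 1.60 ± 0.35. Pdgfrb, a growth factor receptor of stellate cells, rose from 10.1 ± 2.53 to 28.55 ± 7.05 CPM. In vehicle replicate 2, Col1a1, Col1a2, Col3a1, Pdgfrb, Timp1 and the scores of both lists were the lowest of their group.

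Of 27 lipid-associated macrophage markers, 24 rose and 1 fell (25 and 2 adjusted over the list alone), with a median of 2.71. Camera called the list with the preset and with the estimated correlation (adjusted p = 9.42e-18 and 0.0367). Trem2, a lipid-sensing receptor of these cells, rose by 4.95 ± 0.39, from 0.989 ± 0.763 to 31.5 ± 15.3 CPM. Cd68, a lysosomal glycoprotein, rose by 2.71 ± 0.16. Of 18 Kupffer cell markers, 11 rose and 1 fell (11 and 1 adjusted over the list alone), a list called by camera (adjusted p = 0.000201), with adjusted p = 0.372 with an estimated correlation. Cd5l, an apoptosis inhibitor secreted by macrophages, rose by 2.76 ± 0.23 and Csf1r, the receptor of macrophage colony-stimulating factor, by 1.72 ± 0.14. Of the 18 Kupffer cell markers, 6 had a negative log2 fold change. Among them, named after its values were seen, was Cd163, a scavenger receptor, which averaged 14.16 ± 7.46 CPM in lean chow and 0.454 ± 0.632 CPM in vehicle. Of 24 chemokines and cytokines, 17 rose and 1 fell (18 and 2 adjusted over the list alone), with camera adjusted p = 1.48e-07 and adjusted p = 0.0709 with an estimated correlation. Il1rn, the interleukin-1 receptor antagonist, rose by 2.76 ± 0.23 and Ccl6, a macrophage chemokine, by 2.64 ± 0.23.

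Of 25 cholesterol synthesis genes, 0 rose and 23 fell (0 and 24 adjusted over the list alone), with a median of -1.74. Camera called the list (adjusted p = 5.84e-16), with adjusted p = 0.126 with an estimated correlation. Tm7sf2, a sterol reductase, changed by -2.51 ± 0.22. Of 26 growth hormone responsive, male-biased genes, 1 rose and 24 fell (1 and 24 adjusted over the list alone), with a median of -1.94, camera adjusted p = 1.27e-10 and adjusted p = 0.240 with an estimated correlation. Of 38 cytochrome P450 and drug metabolism genes, 3 rose and 23 fell (3 and 23 adjusted over the list alone), with camera adjusted p = 3.24e-05 and adjusted p = 0.275 with an estimated correlation. Cyp1a2, which metabolises caffeine, changed by -1.32 ± 0.17 and Ugt2b5, a glucuronosyltransferase, by -1.02 ± 0.13. Of 29 bile acid genes, 3 rose and 18 fell (3 and 18 adjusted over the list alone), with camera adjusted p = 0.000657 and adjusted p = 0.372 with an estimated correlation. Cyp7b1, the oxysterol hydroxylase of the alternative bile acid pathway, changed by -2.04 ± 0.22 and Baat, which conjugates bile acids, by -0.73 ± 0.11. In lean chow, replicate 2 was the lowest library in Hsd3b5, Serpina1e, Tm7sf2, Baat and the scores of the cholesterol synthesis and male-biased lists.

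Of 30 lipid droplet and uptake genes, 11 rose and 0 fell (11 and 0 adjusted over the list alone), with camera adjusted p = 0.00411 and adjusted p = 0.372 with an estimated correlation. Lpl, lipoprotein lipase, rose by 3.48 ± 0.30 and Cidec, a lipid droplet fusion protein, by 3.20 ± 0.28. Of 26 fatty acid synthesis genes, 5 rose and 6 fell (5 and 6 adjusted over the list alone), and camera did not call the list (adjusted p = 0.674). Scd2, a stearoyl-CoA desaturase, rose by 2.34 ± 0.19, and Acss2, an acetyl-CoA synthetase, changed by -1.97 ± 0.36. Of 37 fatty acid oxidation and PPAR alpha target genes, 1 rose and 11 fell (1 and 11 adjusted over the list alone, camera adjusted p = 0.119). The 1 that rose was Vnn1, a pantetheinase, by 1.06 ± 0.22, while Acot1, an acyl-CoA thioesterase, changed by -1.27 ± 0.24. Of 33 acute phase and complement genes, 9 rose and 10 fell (9 and 10 adjusted over the list alone, camera adjusted p = 0.304). Saa2, a serum amyloid, rose by 3.64 ± 0.32 and Orm2, an acid glycoprotein, by 2.62 ± 0.28. Cyp7a1, the rate-limiting enzyme of bile acid synthesis, at 0.18 ± 0.37, Fgf21, a liver hormone of fasting, at 0.39 ± 0.45, and Gcgr, the glucagon receptor, at -0.38 ± 0.16, did not pass (edgeR adjusted p = 0.721, 0.519 and 0.0547). Fgf21 stood at 0.99 without lean chow replicate 2 (edgeR adjusted p = 0.0536), at -0.28 with length and GC covariates, and was called by voom at 1.80 (adjusted p = 2.04e-05). Cyp7a1 stood at -0.19 without vehicle replicate 3. Gcgr passed by edgeR without lean chow replicate 2 or vehicle replicate 2, 4 or 5 (adjusted p = 0.0230 to 0.0393). It also passed by voom, and by edgeR with the covariates and with the replicate block (adjusted p = 6.12e-05, 0.00137 and 0.02595).

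Cell cycle genes were called by camera with the preset and with the estimated correlation (adjusted p = 3.60e-12 and 0.0439), and 26 of 30 rose and 0 fell (26 and 0 adjusted over the list alone). Dendritic cell and antigen presentation genes had 14 of 21 risen and 0 fallen (17 and 0 adjusted over the list alone), with adjusted p = 0.104 with an estimated correlation. Interferon-stimulated genes had 23 of 32 risen and 1 fallen (24 and 1 adjusted over the list alone), with adjusted p = 0.104 with an estimated correlation. Cholangiocyte markers had 15 of 20 risen and 0 fallen (16 and 0 adjusted over the list alone), and T and NK cell markers 9 of 20 and 0 (9 and 0 adjusted over the list alone). For these lists adjusted p = 0.414 and adjusted p = 0.372 with an estimated correlation. Hepatocyte secreted and lipoprotein genes had 1 of 31 risen and 20 fallen (1 and 20 adjusted over the list alone), and oxidative phosphorylation genes 0 of 49 and 11 (0 and 10 adjusted over the list alone), with adjusted p = 0.372 and adjusted p = 0.597 with an estimated correlation. Unfolded protein response genes had 0 of 26 risen and 13 fallen (0 and 13 adjusted over the list alone), and gluconeogenesis and insulin response genes 2 of 26 and 10 (2 and 11 adjusted over the list alone). Their calls gave adjusted p = 0.414 and adjusted p = 0.372 with an estimated correlation. The p53 targets, with 5 of 17 risen and 2 fallen (5 and 2 adjusted over the list alone), and adipocyte genes, with 3 of 6 and 0 (3 and 0 adjusted over the list alone), were also called, with adjusted p = 0.490 and adjusted p = 0.275 with an estimated correlation.

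The slope of log2 CPM on GC content averaged -0.0711 ± 0.0752 in lean chow, 0.0368 ± 0.0724 in vehicle and 0.0343 ± 0.114 in semaglutide (SD, n = 8 each). Against lean chow, exact permutation gave p = 0.0131 for vehicle (adjusted p = 0.0783) and p = 0.0357 for semaglutide (adjusted p = 0.129), so the slope was partly confounded with the diet. With the length and GC slopes as covariates, added after seeing the data, cholangiocyte markers had a median of 0.19 in place of 1.45, with 3 risen and 2 fallen, and were no longer called (camera adjusted p = 0.242). Unfolded protein response genes (median -0.17 in place of -0.355, 7 fallen), gluconeogenesis genes (-0.15 in place of -0.30) and p53 targets (0.17 in place of 0.275, 2 risen) also lost their camera calls (adjusted p = 0.175, 0.190 and 0.168). Oxidative phosphorylation genes kept theirs with a median of -0.09 in place of -0.29 (camera adjusted p = 0.00926), while T and NK cell markers had 5 risen and bile acid genes 11 fallen. Without lean chow replicate 2, adipocyte genes were no longer called (camera adjusted p = 0.0796), 7 unfolded protein response genes and 23 oxidative phosphorylation genes fell, and 12 p53 targets rose. Without vehicle replicate 2, 20 oxidative phosphorylation genes fell. The replicate block ended the call of p53 targets (camera adjusted p = 0.0517). Of the calls with an estimated correlation, those of lipid-associated macrophage markers and cell cycle genes were lost with the covariates (camera adjusted p = 0.0769 each), and that of stellate cell markers held (0.0230). The change itself stayed near its size in the first 2 lists, with medians of 2.33 in place of 2.71 (24 risen) and 1.44 in place of 1.47 (23 risen).

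Camera with the preset correlation called 21 of 36 lists, 13 up and 8 down, of which 3 held with an estimated correlation. Fry, which does not compare a list with other genes, called 25 of the 36. Among them were collagen and matrix genes (fry adjusted p = 8.39e-09) and cholesterol synthesis genes (2.86e-07). Lists not called, counted as members risen and fallen, were sinusoidal endothelial markers (9 and 3 of 25), B and plasma cell markers (2 and 4 of 13), neutrophil markers (2 and 0 of 4) and NRF2 targets (9 and 4 of 25). The same held for pericentral (3 and 8 of 22) and periportal (2 and 12 of 22) hepatocyte markers, female-biased genes (3 and 1 of 10) and clock genes (1 and 6 of 21). It also held for red blood cell (0 and 1 of 6), pancreas (0 and 1 of 1), gallbladder and intestine (1 and 0 of 2) and muscle genes (0 and 0 of 1). Adjusted over the list alone, the endothelial (9 and 4), B cell (2 and 5), NRF2 (10 and 4), pericentral (3 and 9) and periportal (2 and 13) lists differed from these counts. Camera called the periportal list down without lean chow replicate 2 (adjusted p = 0.00152) and without vehicle replicate 2 (0.0203), and NRF2 targets up (0.0293) and the 1 pancreas gene down (0.0202) without lean chow replicate 2. Without lean chow replicate 2, an alternative chosen after seeing the data, 2897 genes were higher and 2763 lower.

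The second comparison asked how semaglutide changed MASH livers relative to vehicle. Macrophage, matrix and lipid genes were among those that fell, and 2 male-biased liver genes were among those that rose. Cd68 fell from 52.9 ± 12.0 CPM in vehicle to 32.9 ± 8.17 CPM in semaglutide (SD, n = 8 each, lean chow 8.06 ± 1.47). Cd5l fell from 450.7 ± 150.3 to 227.5 ± 82.9 CPM, against 66.4 ± 7.34 CPM in lean chow. Rdh16f2, a retinol dehydrogenase family member, rose from 43.5 ± 23.1 to 101.9 ± 18.8 CPM, against 154.9 ± 33.1 CPM in lean chow. By edgeR quasi-likelihood with Benjamini-Hochberg adjustment, 19 genes were higher and 67 lower in semaglutide, 9 and 22 of them at least 2-fold, and 1776 had an unadjusted p under 0.05.

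Rises and falls were ranked among called genes with a mean log2 CPM of at least 2 and a named symbol. The largest rises were of Serpina4-ps1 (ENSMUSG00000092075, chromosome 12, 104080649 to 104086724), annotated as an unprocessed pseudogene, by 3.63 ± 0.86 (log2 fold change and SE). It averaged 1.48 ± 1.37 CPM in vehicle and 17.98 ± 34.5 CPM in semaglutide, where replicate 1 held 102.1 CPM, and without that library the log2 fold change was 2.05 and did not pass (edgeR adjusted p = 0.207). Igha, the immunoglobulin A constant region, rose by 2.11 ± 0.50. Cyp4a14, a fatty acid hydroxylase induced by PPAR alpha, rose by 1.56 ± 0.36, Sox12, a transcription factor, by 1.35 ± 0.30, and Rdh16f2 (ENSMUSG00000074639, chromosome 10, 127866474 to 127877317) by 1.23 ± 0.21. Vehicle replicate 2 was the highest of its group in Rdh16f2, and vehicle replicate 5 was the lowest in Igha. The largest falls were of Themis (ENSMUSG00000049109, chromosome 10, 28668360 to 28883818), a thymocyte signalling protein, at -1.84 ± 0.39, and Cntnap1 (ENSMUSG00000017167, chromosome 11, 101170523 to 101190724), a contactin-associated protein, at -1.55 ± 0.28. Fam83a, a signalling adaptor, reached -1.53 ± 0.36, Gsta1, a glutathione transferase, -1.36 ± 0.27, and Anxa2, a membrane-binding annexin, -1.33 ± 0.28. Vehicle replicate 2 was the lowest of its group in Cntnap1 and Fam83a. With the length and GC covariates Serpina4-ps1 at 2.54 and Fam83a at -1.30 did not pass (edgeR adjusted p = 0.138 and 0.0964).

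**Figure D2:**
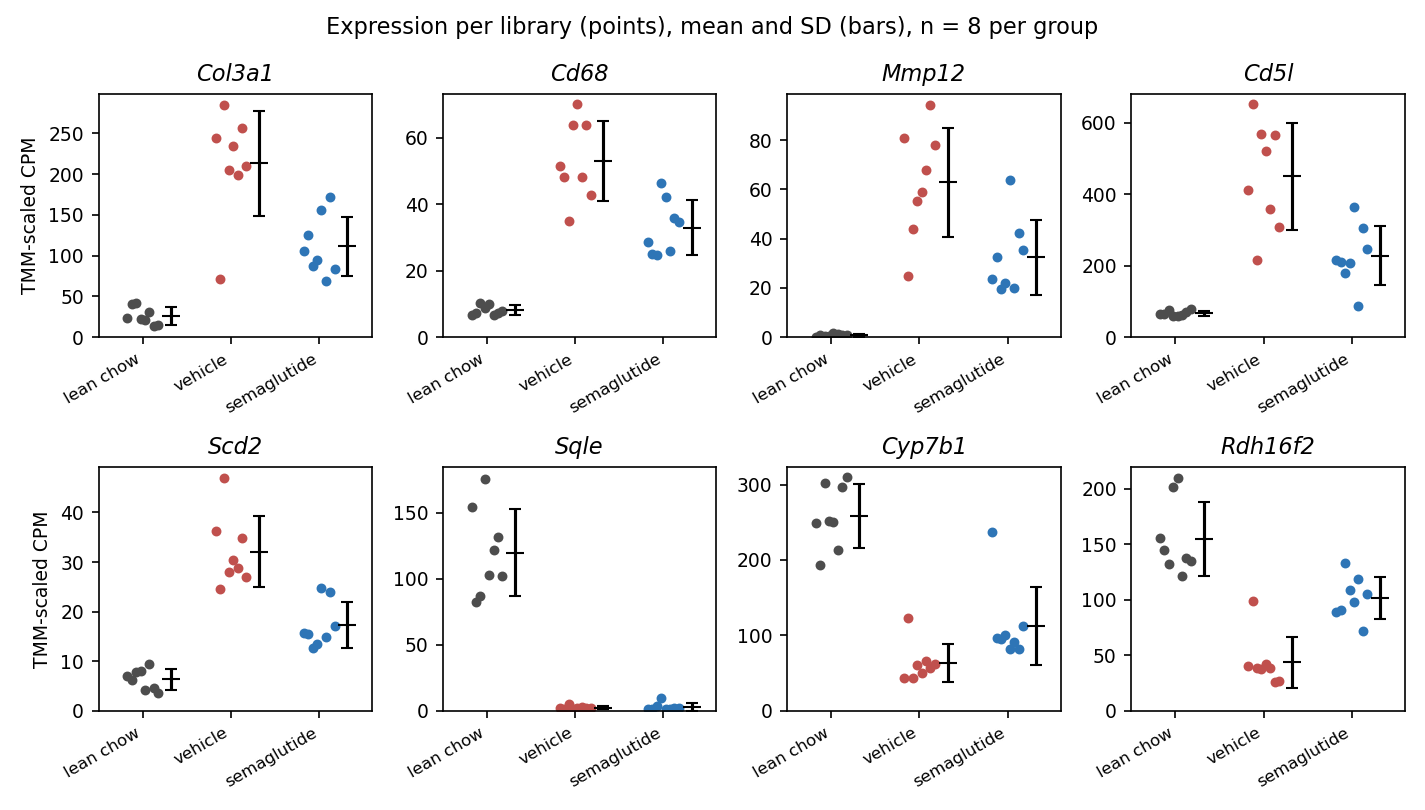
TMM-scaled CPM of 8 genes in each of the 24 libraries, 1 panel per gene, with the mean and SD of each group of 8. Cd68 averaged 8.06 CPM in lean chow, 52.9 in vehicle and 32.9 in semaglutide, while Sqle averaged 119.6, 2.24 and 2.77 CPM.

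Of 40 collagen and matrix genes, 0 rose and 4 fell (0 and 20 adjusted over the list alone), and 35 had a negative log2 fold change, with a median of -0.49. Camera called the list (adjusted p = 9.78e-12), with adjusted p = 0.397 with an estimated correlation. Tnc, the matrix glycoprotein tenascin C, fell at -1.31 ± 0.30 and Col4a1, a basement membrane collagen chain, at -0.83 ± 0.19. The other members past the threshold, named after their values were seen, were Col4a2 at -0.76 and Col5a1 at -0.65. Col4a1 and Col4a2 overlap on opposite strands. With the length and GC covariates Tnc at -1.22 and Col4a1 at -0.57 did not pass (edgeR adjusted p = 0.0502 and 0.0869). The 4 members past the threshold became 2 with these covariates, 10 without lean chow replicate 2 and 11 without vehicle replicate 2. Col1a1 at -0.76 ± 0.29 and Timp1 at -0.85 ± 0.34 did not pass (edgeR adjusted p = 0.235 and 0.254). Of 27 stellate cell markers, 0 rose and 0 fell (0 and 0 adjusted over the list alone) by edgeR, the list median was -0.06, and Acta2 stood at -0.37 ± 0.33 (adjusted p = 0.648).

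All 27 lipid-associated macrophage markers had a negative log2 fold change, with a median of -0.45, and 0 rose and 1 fell (0 and 7 adjusted over the list alone). The list was called by camera (adjusted p = 6.73e-10), with adjusted p = 0.260 with an estimated correlation. The member that fell was Cd68, at -0.68 ± 0.15, whereas Trem2 at -0.55 ± 0.30 did not pass (edgeR adjusted p = 0.427). The count of 1 became 3 with the covariates and 4 without vehicle replicate 2. Of 18 Kupffer cell markers, 0 rose and 2 fell (0 and 5 adjusted over the list alone), Cd5l at -0.99 ± 0.21 and Csf1r at -0.62 ± 0.14. Camera called this list (adjusted p = 0.00325), with adjusted p = 0.677 with an estimated correlation and 0.0885 without vehicle replicate 2, and with the covariates 8 members fell. Dendritic cell genes (0 and 0 of 21, also adjusted over the list alone), interferon-stimulated genes (0 and 0 of 32, also adjusted over the list alone) and chemokines (0 and 0 of 24, 0 and 2 adjusted over the list alone) had medians of -0.38, -0.23 and -0.11. Camera called all 3 down (adjusted p = 0.0190, 0.00371 and 0.0275), each with adjusted p = 0.677 with an estimated correlation. Cell cycle genes had a median of -0.55, with 0 of 30 risen and 0 fallen (0 and 6 adjusted over the list alone), camera adjusted p = 8.67e-09 and adjusted p = 0.260 with an estimated correlation.

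All 26 male-biased, growth hormone responsive genes had a positive log2 fold change, with a median of 0.76, and 2 rose and 0 fell (13 and 0 adjusted over the list alone). They were Serpina4-ps1 and, named after its values were seen, C8b, a complement component, at 0.98. The count of 2 became 11 without vehicle replicate 2, 8 without lean chow replicate 2 and 0 with the covariates, and the score had an SD of 1.03 between semaglutide libraries. Semaglutide replicate 1 stood above the rest of its group in the members Hsd3b5 (5.71 log2 CPM, others at most 1.32) and Cyp7b1 (7.89, others at most 6.82). The list was not tested without that library, so how far the rise is shared by the group is not known. Camera called the list (adjusted p = 3.88e-08), with adjusted p = 0.677 with an estimated correlation. Hepatocyte secreted genes (0 and 0 of 31), P450 genes (0 and 0 of 38) and oxidative phosphorylation genes (0 and 0 of 49) had no member past the threshold, also when adjusted over the list alone, although 4 secreted and 5 P450 genes passed without vehicle replicate 2. Their medians were 0.28, 0.22 and 0.23, and camera called all 3 up (adjusted p = 8.69e-07, 0.00223 and 1.19e-08), each with adjusted p = 0.677 with an estimated correlation. With the length and GC slope of each library as covariates, the oxidative phosphorylation list had a median of 0.03 and was no longer called (camera adjusted p = 0.128). NRF2 targets had 0 of 25 risen and 1 fallen, Gsta1 (0 and 1 adjusted over the list alone), with camera adjusted p = 0.00319 and adjusted p = 0.260 with an estimated correlation.

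Cholesterol synthesis genes, which had fallen in vehicle livers, had 0 of 25 risen and 0 fallen (0 and 0 adjusted over the list alone), with a median of 0.10 and camera adjusted p = 0.253. Bile acid genes had 0 and 0 of 29 (2 and 0 adjusted over the list alone), and Cyp7a1 stood at 0.16 ± 0.37 (edgeR adjusted p = 0.884). Scd2 fell at -0.89 ± 0.18 as the 1 member of 26 fatty acid synthesis genes to pass (0 and 1 adjusted over the list alone), and Mogat1, a monoacylglycerol acyltransferase, at -1.32 ± 0.31 as the 1 of 30 lipid droplet genes (0 and 5 adjusted over the list alone). Cyp4a14 was the 1 of 37 fatty acid oxidation genes to pass (3 and 0 adjusted over the list alone). Saa3, a serum amyloid of inflamed tissue, rose by 1.06 ± 0.25 as the 1 of 33 acute phase genes to pass (1 and 0 adjusted over the list alone). Igha was the 1 of 13 B and plasma cell markers (1 and 0 adjusted over the list alone). T and NK cell markers had 0 and 0 of 20 (0 and 0 adjusted over the list alone) and cholangiocyte markers 0 and 0 of 20 (0 and 1 adjusted over the list alone). Fgf21 at -0.23 ± 0.45 and Gcgr at 0.18 ± 0.16 did not pass (edgeR adjusted p = 0.862 and 0.645). Glp1r, the receptor of semaglutide, held 0 to 10 counts per library, too few to be tested, with sums of 4 in lean chow, 17 in vehicle and 26 in semaglutide.

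**Figure D3:**
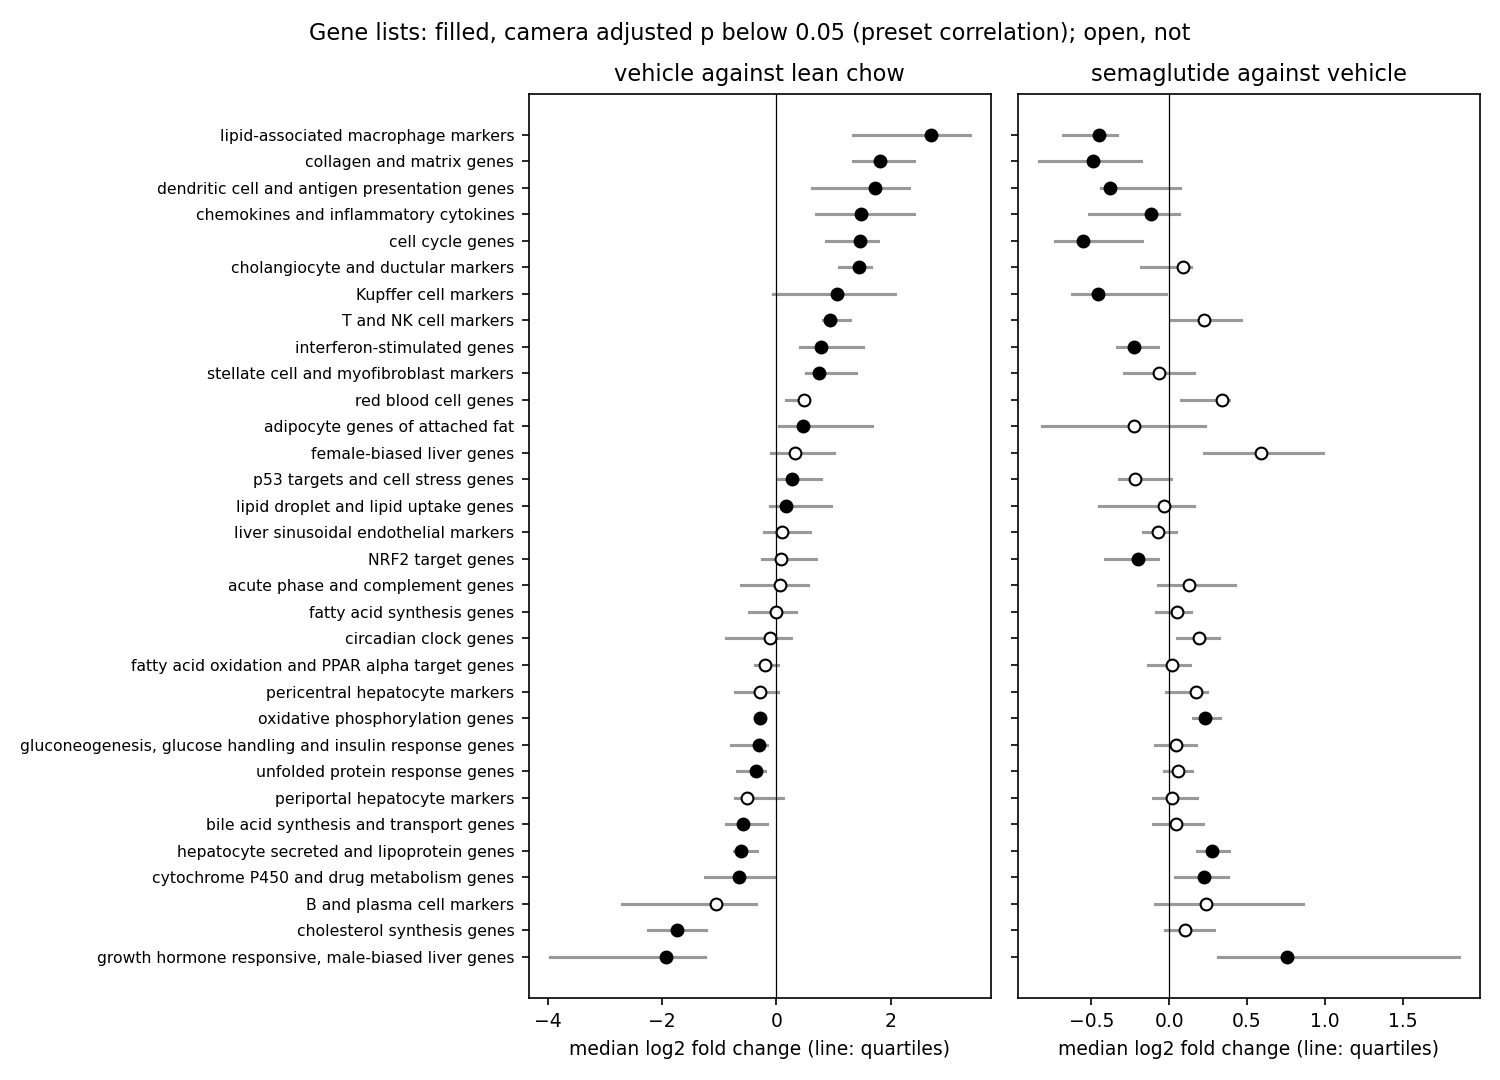
Median log2 fold change of the tested members of each gene list with at least 5 of them, with quartiles as lines and camera calls with the preset correlation as filled points. Lipid-associated macrophage markers had a median of 2.71 in vehicle against lean chow and -0.45 in semaglutide against vehicle, and cholesterol synthesis genes -1.74 and 0.10.

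Camera called 12 of 36 lists, 4 up and 8 down, of which 0 held with an estimated correlation after adjustment, although 4 had an unadjusted p under 0.05, and fry called 3. Lists not called, counted as members risen and fallen, also included sinusoidal endothelial markers (0 and 1 of 25), neutrophil markers (0 and 0 of 4), p53 targets (0 and 0 of 17) and unfolded protein response genes (0 and 0 of 26). Others were gluconeogenesis genes (1 and 0 of 26), pericentral and periportal hepatocyte markers (0 and 0 of 22 each), female-biased genes (1 and 0 of 10) and clock genes (0 and 0 of 21). Red blood cell and adipocyte genes (0 and 0 of 6 each), pancreas and muscle genes (0 and 0 of 1 each) and gallbladder genes (0 and 0 of 2) completed them. Adjusted over the list alone, the gluconeogenesis (2 and 0), pericentral (3 and 1), periportal (0 and 2), female-biased (2 and 0) and adipocyte (0 and 1) lists differed from these counts. Fatty acid synthesis, cholangiocyte and periportal lists had positive medians (0.049, 0.088 and 0.016) while camera gave them a downward direction without a call. With the covariates camera also called lipid droplet, periportal and adipocyte genes down (adjusted p = 0.000940, 0.0110 and 0.00670) and female-biased genes up (0.0308). Without lean chow replicate 2 or vehicle replicate 2 it called p53 targets down (adjusted p = 0.0169 and 0.0482) and pericentral markers up (0.0396 and 0.0170), and without the latter cholangiocyte markers down (0.0482). The counts depended on single libraries: 120 higher and 192 lower without vehicle replicate 2, 92 and 163 without lean chow replicate 2, and 3 and 10 without vehicle replicate 1. With 1 library left out at a time, Cntnap1 and Rdh16f2 passed in 16 of 16 fits, Gsta1 in 10, Scd2 in 9, Cd5l in 8, Anxa2 and Csf1r in 7, Cd68, Cyp4a14, Sox12 and Themis in 6, Col4a1, Tnc and Serpina4-ps1 in 5, Fam83a, Igha and Saa3 in 4, and Mogat1 in 3.

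The third comparison asked how far semaglutide livers still differed from lean chow livers. Most lipid-associated macrophage markers and collagen and matrix genes were higher, and most cholesterol synthesis genes lower, in semaglutide than in lean chow. Trem2 stood at 21.4 ± 10.4 CPM in semaglutide and 0.989 ± 0.763 CPM in lean chow (SD, n = 8 each). Col1a1 stood at 81.2 ± 27.2 CPM and 10.8 ± 5.93 CPM, and Sqle at 2.77 ± 2.85 CPM and 119.6 ± 32.8 CPM. By edgeR quasi-likelihood with Benjamini-Hochberg adjustment, 2072 genes were higher and 1727 lower in semaglutide, 1153 and 235 of them at least 2-fold.

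The ranking again took called genes with a mean log2 CPM of at least 2 and a named symbol. The highest log2 fold changes were of Ephb2 at 5.72 ± 0.61 (SE, n = 8 per group), Mmp12 at 5.29 ± 0.37, H19 at 5.22 ± 0.92 (4.01 without semaglutide replicate 4), Gpnmb at 4.91 ± 0.51 (6.50 without lean chow replicate 5) and Trem2 at 4.39 ± 0.39. Those of Ephb2 and H19 rest on lean chow means of 0.226 and 0.120 CPM. Timp1 was higher by 3.51 ± 0.46, Col1a1 by 2.90 ± 0.32 and Acta2 by 1.23 ± 0.35. The lowest were of Sqle at -5.43 ± 0.39 (-6.05 without semaglutide replicate 4), Cd163, a haemoglobin scavenger receptor of Kupffer cells, at -4.44 ± 0.57, and Hsd3b5 at -4.05 ± 0.93. Idi1, an isomerase of cholesterol synthesis, reached -3.89 ± 0.34 and Cyp2b10, a drug-inducible P450, -3.77 ± 0.81. Cyp2b10 averaged 33.6 ± 73.8 CPM in lean chow, with replicate 2 far above the other 7, and 2.44 ± 1.25 CPM in semaglutide, and its log2 fold change without that library was -1.60. Hsd3b5 was highest in semaglutide replicate 1, far above the other 7 of its group, and stood at -7.32 without that library. Cyp7a1 at 0.34 ± 0.37, Fgf21 at 0.16 ± 0.46 and Gcgr at -0.20 ± 0.16 did not pass (edgeR adjusted p = 0.513, 0.825 and 0.341). Fgf21 stood at 0.76 without lean chow replicate 2 (edgeR adjusted p = 0.165), at -0.0064 without semaglutide replicate 4 and at -0.34 with the length and GC covariates, and was called by voom at 1.27 (adjusted p = 0.00454). Gcgr passed with the covariates (edgeR adjusted p = 0.00150).

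Of 40 collagen and matrix genes, 37 were higher and 1 lower (37 and 1 adjusted over the list alone), and of 27 lipid-associated macrophage markers 23 and 1 (23 and 2 adjusted over the list alone), with medians of 1.47 and 2.07. Camera called both (adjusted p = 1.06e-20 and 1.12e-16), with adjusted p = 0.0711 and adjusted p = 0.0490 with an estimated correlation, the latter 0.127 with the covariates, where the macrophage median stayed near its size at 1.92 and 23 were higher. Cholesterol synthesis genes had 0 of 25 higher and 24 lower (0 and 25 adjusted over the list alone), with a median of -1.66 and adjusted p = 0.0711 with an estimated correlation. Stellate cell markers had 14 of 27 higher and 0 lower (15 and 1 adjusted over the list alone), a call that held with an estimated correlation (adjusted p = 0.00570). Cell cycle genes had 16 of 30 higher and 0 lower (21 and 0 adjusted over the list alone), dendritic cell genes 15 of 21 and 0 (16 and 0 adjusted over the list alone), and chemokines 16 of 24 and 0 (18 and 0 adjusted over the list alone). For each of these 3 lists adjusted p = 0.0711 with an estimated correlation. Camera called 22 of 36 lists, 13 up and 9 down, of which 2 held with an estimated correlation, and fry called 21 of the 36. B and plasma cell (-0.73), muscle (-0.20) and sinusoidal endothelial (-0.017) lists had negative medians while camera gave them an upward direction without a call.

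Of the 2630 genes higher in vehicle than in lean chow, 64 were lower in semaglutide than in vehicle, where independent lists share 13.2. Of the 2622 genes lower in vehicle, 15 were higher in semaglutide, where independent lists share 3.73. The 1 gene higher in both was Saa3, and 0 genes were lower in both by the edgeR calls. The shared vehicle libraries favour opposite calls, which the counts for independent lists leave out. With 1 library left out, the 64 became 9 (vehicle replicate 1) to 184 (vehicle replicate 2) and the 15 became 2 to 106, moving by over 1.5 times in 17 and 19 of 24 fits. With even replicates of vehicle for the diet and odd for semaglutide, 23 and 5 genes were called in opposite directions, against 3.40 and 0.479 expected if the calls were independent. The other way round, with the even replicates, vehicle replicate 2 among them, for semaglutide, 1 gene was lower in semaglutide and 0 were called in opposite directions. Among the 64 genes, which include Cd68, Cd5l, Scd2 and Anxa2, 54 were still called against lean chow, and among the 15, which include Rdh16f2 and Serpina4-ps1, 4 were. Of all genes higher and lower in vehicle, 72.4% and 53.7% were still called against lean chow.

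Both fold changes use the same vehicle libraries, which alone gives them a negative covariance. Across genes it was -0.150, against -0.0247 in simulated data without an effect. With separate vehicle libraries for each fold change, the covariance averaged -0.130 over 70 splits (range -0.185 to -0.0634), and permuting the vehicle and semaglutide labels gave an exact two-sided p = 0.00559. With genes chosen in one set of vehicle replicates and measured in the other, the opposite semaglutide change amounted to 15.9% and 29.7% of the median rise, and to 19% and 25.7% of the median fall. The first value of each pair was measured on the even replicates, vehicle replicate 2 among them. The same lean chow libraries served to choose and to measure, so the rise and fall keep part of the selection.

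**Figure D4:**
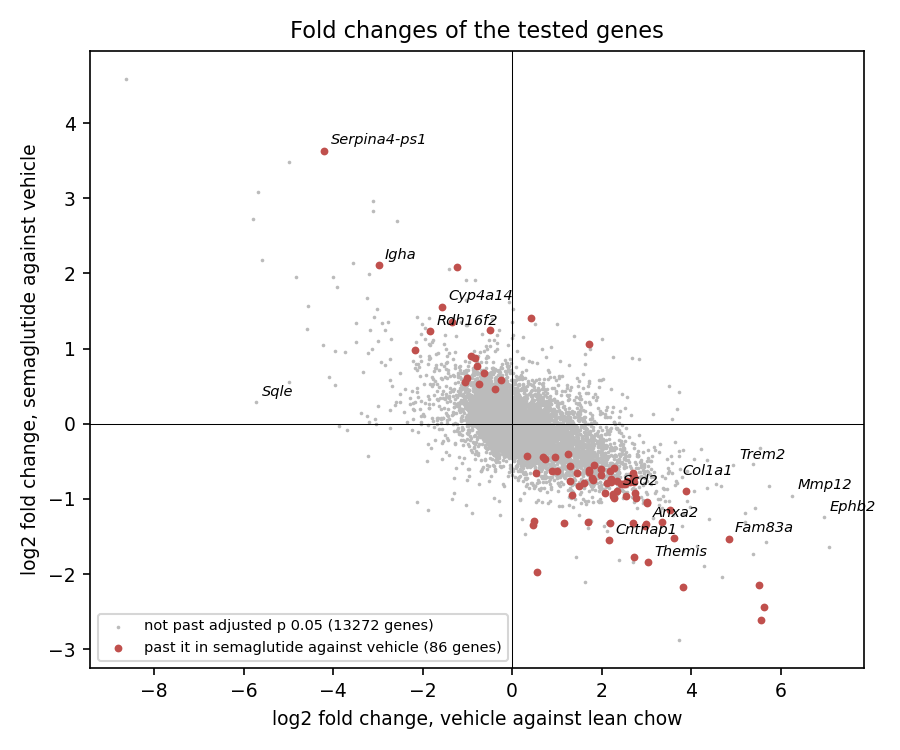
Log2 fold change of semaglutide against vehicle plotted on that of vehicle against lean chow for 13358 tested genes, with the 86 genes called in semaglutide against vehicle in red. Of the red genes, 64 were higher in vehicle and lower with semaglutide, and 15 the reverse.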

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

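The tests of position between groups, of swapped samples, of mixing with lean chow RNA, of abundant lean chow transcripts, of the trend in list scores of vehicle replicate 2 and of other cell types were chosen only after the result was seen. The bound for the swap and the list score test replaced earlier ones whose values had been seen. Of 291 groups of 8 libraries tested, 52 had a library whose gap to its nearest neighbour exceeded Dixon's critical value of 0.526 of the range, where chance gives about 14.55. Lean chow replicate 2 and vehicle replicate 2 account for 21 each. Many of these measures share genes, so they are not independent.

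Lean chow replicate 2 was the lowest of its group in Acss2 (ratio 0.623), Baat (0.639), Hsd3b5 (0.829), Serpina1e (0.565), Serpina4-ps1 (0.571) and Tm7sf2 (0.744). It was the highest in Anxa2 (0.622), Col4a1 (0.658) and Cyp2b10 (0.644). Among list scores it was the lowest for adipocyte genes (0.789), cholesterol synthesis (0.553), gluconeogenesis (0.576), male-biased genes (0.705), hepatocyte secreted genes (0.590), Kupffer cell markers (0.690) and periportal markers (0.795). It was the highest for p53 targets (0.788) and the unfolded protein response (0.647). It also stood out in albumin share (0.753, lowest), the share of the top 20 genes (0.614, lowest) and the TMM factor (0.756, highest).

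For lean chow replicate 2, 225 of 13358 genes were at least 4-fold above the mean of the other 7 libraries and 245 at least 4-fold below it. Its p53 score was 1.35, against -0.61 on average in the others. A MASH library under a lean chow label is argued against by its median position of 0.303 from lean chow (0) to vehicle (1), where the lowest MASH library lay at 0.651. A length and GC trend is argued against by its distance from the others, 1.60 times the largest among them with the trend removed. Of 16 detected blood, fat, pancreas, gut and muscle genes, 0 were 4-fold raised. Blood is argued against, since its haemoglobin genes were no higher here (log2 difference -0.39 for Hbb-bs to -0.64 for Hbb-bt). For fat, pancreas, gut and muscle the count cannot decide, since the expression filter removes a transcript found only in this library. A stressed or ill animal may account for the pattern, but no biological explanation was tested.

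Vehicle replicate 2 was the lowest of its group in Cntnap1 (0.5998), Col1a1 (0.578), Col1a2 (0.710), Col3a1 (0.741), Col4a1 (0.569), Ephb2 (0.774) and Fam83a (0.737). The same held for Gpnmb (0.615), Il1rn (0.614), Pdgfrb (0.617), Timp1 (0.548) and Vnn1 (0.644), and for the scores of collagen and matrix genes (0.681), lipid-associated macrophage markers (0.553), p53 targets (0.544) and stellate cell markers (0.691). It was the highest in Cyp7b1 (0.5999), Hsd3b5 (0.595), Rdh16f2 (0.622), Serpina1e (0.666) and Ugt2b5 (0.538).

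Vehicle replicate 2 lay at 0.621 from lean chow (0) to vehicle (1), and a swap with a semaglutide library stays open: the highest of those (0.857) lay below the lowest other vehicle library (0.904) by less than the SD of the other 7 (0.0683), and exchanging it with each in turn gave 4 to 395 genes, against 312 with it left out. Lean chow RNA mixed into the sample was weighed by the share it would need. Genes higher in vehicle implied a median of 59.2% (quartiles 29.6 to 85.1). Genes lower in vehicle implied 19.9% (6.84 to 47.8), which is 39.3 points less, but the quartile ranges overlapped. Of 34 abundant lean chow transcripts that were lower in vehicle, 3 reached the level that 59.2% needs. Their median share was 22.1% (quartiles 6.83 to 37.6), which argues against mixing at 59.2%, the share implied by genes higher in vehicle. Mixing at a smaller share stays open. A length and GC trend is argued against as the whole cause for the collagen and matrix score, whose ratio with the trend removed was 0.677 (95% interval 0.565 to 0.770 over genes resampled as if independent, which leaves out the spread between libraries). It cannot be told apart for the macrophage (0.623, 0.395 to 0.755), stellate cell (0.534, -0.530 to 0.719) and p53 scores (0.388, -0.246 to 0.662), whose intervals span 0.526, nor over all genes, where the distance was 1.12 times the largest among the others before and 1.25 after, too near 1 for the bound of 1.5 to be reached. A milder disease course in that animal may also account for it, and no biological explanation was tested.

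The third pattern is the set of lists called in semaglutide against vehicle. With the length and GC slopes of the libraries as covariates, medians were -0.36 for collagen and matrix genes, -0.46 for lipid-associated macrophage markers, -0.51 for cell cycle genes, 0.54 for male-biased genes and 0.15 for hepatocyte secreted genes, and all 5 remained called by camera with the preset correlation, which argues against that trend as the whole cause, although with an estimated correlation none was called (adjusted p = 0.260 to 0.677 without the covariates and 0.220 to 0.763 with them). For oxidative phosphorylation genes the median dropped from 0.23 to 0.028, 12.3% of its size, and the call ended because the change itself shrank, so the trend may account for it, although 10000 random lists matched on length and GC had a median of 0.13 and the list lay at their percentile 99.3. A lower share of all non-hepatocyte cells is argued against for the macrophage list, whose score changed by -0.50 relative to T and NK and stellate markers (exact permutation p = 0.000311). That p is not adjusted for the choice of these markers, made after the result was seen. The scores left out changed by -0.09 (sinusoidal endothelial), -0.02 (cholangiocyte), -0.27 (Kupffer cell) and 0.32 (B and plasma cell). A response to semaglutide or to lower body weight stays open, and the latter was not tested.

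Other libraries past the critical value are given as values. Lean chow replicate 3 was the highest in B and plasma cell (0.612), dendritic cell (0.637) and T and NK cell (0.587) scores, and lean chow replicate 5 in Gpnmb (0.660). Semaglutide replicate 1 was the highest in Cyp7b1 (0.696), Hsd3b5 (0.528) and the unfolded protein response score (0.655). Semaglutide replicate 4 was the highest in Gcgr (0.552) and the lowest in the periportal score (0.575). Vehicle replicate 5 was the lowest in Igha (0.544).

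By splits drawn at random, chance is argued against for both counts against lean chow. It is not excluded for the count of semaglutide against vehicle. For vehicle against lean chow, 1 of 100 splits, the real one, gave as many genes (real 5252, highest other 3058). For semaglutide against lean chow it was also 1 of 100 (real 3799, highest other 33). For semaglutide against vehicle it was 2 of 100 (real 86), since the split that exchanged vehicle replicate 2 with semaglutide replicate 7 gave 391 genes. The split with 391 genes gave several times the real count, and leaving vehicle replicate 2 out gave 312. The count thus depends on that library, and what lies behind this was not tested. Exchanging vehicle replicate 2 with semaglutide replicate 2, 4, 5 or 7 gave 395, 204, 315 and 391 genes. With replicate 1, 3, 6 or 8 it gave 4, 33, 25 and 36. Labels other than the real ones can thus call more genes, although 2 of 100 lay under the bound written beforehand.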

How the results depend on the processing

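The tests with length and GC covariates, and the list tests without lean chow replicate 2 or without vehicle replicate 2, were chosen only after the result was seen. No named gene that was called changed sign, and no called list changed camera's direction. By the list median, 2 lists not called by camera in semaglutide against vehicle changed sign where an alternative called them: periportal markers with the covariates (0.016 to -0.093) and cholangiocyte markers without vehicle replicate 2 (0.088 to -0.060). Among those not called, Fgf21 against lean chow did with the covariates, Cyp7a1 and Fgf21 with 1 library left out, and lists in 22 cases. With voom, 52.2% of the genes called in semaglutide against vehicle were higher, against 22.1% by edgeR. For semaglutide against vehicle (19 higher and 67 lower), DESeq2 gave 81 and 226, voom with quality weights 1001 and 918, the fit of only the 2 groups 44 and 133, the covariates 55 and 154, and the replicate block 6 higher. Of the 86 genes, 85 were shared with RLE scaling, DESeq2 and voom each, and 74 with the covariates. For vehicle against lean chow, voom called 4096 lower, and for semaglutide against lean chow voom called 2633 lower and the fit of only the 2 groups 1105. Genes higher with the diet and lower with semaglutide, and the reverse (64 and 15), became 214 and 66 with DESeq2, 779 and 774 with voom, 121 and 32 with the 2 groups, 144 and 40 with the covariates, and 4 of the reverse with the replicate block. They were 23 and 5, or 0 and 0, with separate vehicle replicates for each comparison, where fewer libraries enter each. The cause was not tested in any of these. Other alternatives stayed within 1.5 times.

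Leaving out 1 library, vehicle against lean chow ranged from 2471 to 2897 higher and 2176 to 2763 lower, and semaglutide against lean chow from 1920 to 2291 and 1236 to 1917. Semaglutide against vehicle ranged from 3 to 120 higher and 10 to 192 lower, and the opposite changes from 9 to 184 and 2 to 106. Its higher and lower counts were 3 and 10 without vehicle replicate 1, 120 and 192 without 2, 3 and 15 without 4, 4 and 12 without 5, 6 and 25 without 6, 3 and 10 without 7 and 4 and 30 without 8. Without a semaglutide replicate they were 4 and 10 (replicate 1), 3 and 11 (3), 43 and 121 (5), 4 and 10 (6), 29 and 68 (7) and 4 and 13 (8). Of the 86 genes, 11 were called in all 16 fits and 27 in at least 8.

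Named genes of semaglutide against vehicle lost their call in 11 cases with the replicate block (adjusted p = 0.0521 to 0.175), which were Col4a1, Csf1r, Cyp4a14, Fam83a, Igha, Mogat1, Saa3, Serpina4-ps1, Sox12, Themis and Tnc. With the covariates 4 lost it, Col4a1, Fam83a, Serpina4-ps1 and Tnc, and with voom Serpina4-ps1 lost it and Col1a1, Timp1 and Trem2 gained one. Against lean chow, Acta2 lost its call in semaglutide with voom (adjusted p = 0.0812), and Fgf21 and Gcgr gained one in some settings. Of 12 lists called in semaglutide against vehicle, 0 were called with an estimated correlation, 11 of a total of 15 with the covariates, 12 of 14 without lean chow replicate 2 and 11 of 14 without vehicle replicate 2. Of 21 called in vehicle against lean chow, 17 of 17, 20 of 23 and 21 of 22 were, and of 22 in semaglutide against lean chow 19 of 21, 21 of 23 and 21 of 21. Same-number libraries correlated from -0.371 to 0.614, 3 of 24 correlated best with their own number, and 12 of 24 pairs were over 0.1, among them all 3 pairs of replicate 4 (0.205 to 0.614) and of replicate 8 (0.127 to 0.260). In the simulation of semaglutide against vehicle, with genes drawn independently and no library set apart, 28.4% of 1.5-fold changes were recovered.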

Other observations

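The genes named here were chosen only after the result was seen, and they were tested by the edgeR fit alone. Among the 67 genes lower in semaglutide than in vehicle were 5 single genes outside the gene lists, given as values. Cybb, the catalytic subunit of the phagocyte oxidase, averaged 10.5 ± 3.19 CPM in lean chow, 69.5 ± 15.4 in vehicle and 40.5 ± 9.34 in semaglutide (SD, n = 8 each, log2 fold change -0.78 ± 0.16 against vehicle). Ncf2, another subunit, stood at -0.59 ± 0.14, Gpr35, a G protein-coupled receptor, at -1.15 ± 0.19, Itgb2, the leukocyte integrin beta chain, at -0.80 and Clec7a, a receptor of fungal glucans, at -0.89. Each was also higher in vehicle than in lean chow.

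Among genes that rose were Igfbp2, an insulin-like growth factor binding protein, at 0.88, Slc22a26, a female-biased transporter, at 2.09, and Cyp2c67 and Cyp2c68, at 0.55 and 0.61. The cell type scores of semaglutide minus vehicle were -0.50 for lipid-associated macrophage markers (exact permutation p = 0.0117, adjusted p = 0.0631), 0.32 for B and plasma cell markers (p = 0.0180, adjusted p = 0.0631) and 0.09 for T and NK cell markers, and none passed the adjustment.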
